A study of Mus musculus with 2 samples.

How the data were processed

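Total RNA longer than 200 nt was depleted of ribosomal RNA, selected for poly-A tails and sequenced as stranded pairs of 101 nt reads, per the labels. There are 2 libraries of 1 group, numbered as biological replicates 1 and 2 in the labels. The labels give separate biosamples but do not say how many embryos each held, so p-values measure only the spread between these samples. Expected counts, TPM and FPKM per gene and transcript were deposited for each library on mm10. The aligner and the quantification program are not given in the sources used here.

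The authors also deposited tables of the whole series on mm9. These hold gene values that the files call RPKM, with an irreproducibility score per gene, for Ensembl release 65 and for de novo gene models of Cufflinks, per the file headers and attributes. A junction file gives read counts deposited for 2 replicates and an irreproducibility score, and a contig file a signal level deposited per contig. The replicate numbers of these mm9 files are not tied to a library, so they were never matched to replicate 1 or 2 of the gene tables. Each of the 37310 Ensembl genes is listed on 2 lines and was used once. The mm9 exon file served for exon positions only, and no coordinates were moved between builds.

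The gene tables are based on GENCODE M4, per the deposited read-me texts, and hold 43346 genes, 26248 entries with numeric names, 96 spike-ins and 1 phiX entry. Entries other than genes took 3.62% and 4.01% of the expected counts and stayed out of library sizes and tests. Gene symbols, types and GRCm38 positions came from GENCODE M21, which shares its genome build with mm10, and 42462 genes had a symbol while 884 had none. Of 548 genes in the lists 5 were not found and were not analysed here (Lhfpl3, Ahsp, Rmst, Sox2ot and Peg13). At these depths 3 fragments, the limit that a count of 0 allows, correspond to 0.0319 and 0.0219 CPM, and this covers counting error only.

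Before the data were examined, 41 gene lists, 40 pairs of genes, 50 genes for splicing and the rule for named genes were fixed. The rule names the 10 highest nuclear genes, the highest 2 to 4 members of each list and where it fits the lowest, pairs as needed, per gene the exon with the most junction reads among those at 5% to 95%, and the 5 highest and 5 lowest ratios at a mean TPM of 5 or more. Filters for unannotated transcription (RPKM of 1, 10 reads, contig level of 1 and a score of at most 0.1) were set before those counts were seen but after the files were opened.

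A gene was detected at a TPM of 1 or more in both libraries. Expected counts were rounded for edgeR 4.0.16, with TMM factors, filterByExpr and an intercept-only estimate of the common dispersion, whose square root is the coefficient of variation. Ratios between libraries used CPM scaled by TMM with a prior count of 1. A list's median was placed among 10000 random lists drawn with replacement from 20 bins of level, for lists with at least 5 members at a mean TPM of 1. In the mm9 values the ratios were those of RPKM with a pseudocount of 1, for members at a mean RPKM of 1 or more. Pairs were tested with limma 3.58.1 on log2 ratios with a pseudocount of 1, where no pair fell under the level filter, and called at an adjusted p under 0.05. The estimated prior degrees of freedom were infinite, so all pairs share a pooled SD of 0.21. Inclusion is the mean of both inclusion junction counts over that mean plus the skipping count, at 20 or more junction reads, with Clopper-Pearson intervals. DESeq2 1.42.0 served as an alternative. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and R 4.3.3 were used.

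On simulated data edgeR returned a coefficient of variation of 9.94% for 10% put in over 43346 genes. With 20 of 40 simulated pairs changed by a log2 ratio of 1 and unequal spreads drawn from the observed ones, limma called 90.3% of the changed and 4.20% of the unchanged pairs. Of 1000 random lists of 10 genes 5.50% lay outside the central 95%, and all 20 lists raised by a log2 of 1 did. Of 600 exact intervals on simulated reads 96.7% held the simulated share. A first simulation of pairs with equal spreads had called 100% and 2.70%, and the unequal one was added because it is less favourable.

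Alternatives covered other pseudocounts, filters, scalings, units and leaving out each replicate. Chosen after seeing the data were TPM rescaled over nuclear genes, a correction for GC content and length, leaving out lists of other tissue, turning 5 pairs around, scaling the mm9 values, and asking for balanced inclusion junctions. A further 5 lists (other skeletal muscle, other bone and mesenchyme, liver, heart and epidermis) were written after the ratios of the fixed lists were seen and before their own values were. The results of some genes are not reported here, singly or in the plots of pairs and exons, while counts and medians over lists, pairs and exons include them.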

Results

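Polyadenylated RNA was sequenced from the central nervous system of C57BL/6J mouse embryos at day 18, with 2 libraries from separate biological samples of mixed-sex littermates per the labels. Both libraries form 1 group, so the data describe levels at this age and the difference between the 2 libraries, and hold no comparison between conditions. The gene tables assign 97513548 fragments to replicate 1 and 142741622 to replicate 2, of which 93979836 and 137012773 fall on genes. Levels are the deposited TPM values, which correct for transcript length and library size, and ± gives the SD over n = 2 libraries throughout.

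A total of 14816 genes reached a TPM of 1 in both libraries, and 13506 of them (91.2%) are annotated as protein-coding. Tubulin genes led the nuclear transcripts, with Tuba1a (ENSMUSG00000072235, GRCm38 chromosome 15, 98949837 to 98953703) at 9578 ± 832 TPM and Tubb2b (ENSMUSG00000045136, chromosome 13, 34126748 to 34130466) at 8811 ± 436. Tubb2a stood at 4253 ± 79.4, the translation factor gene Eef1a1 at 5488 ± 353, the ribosomal protein gene Rplp1 at 4312 ± 48.5 and the imprinted gene Nnat at 4546 ± 272. The other 4 of the 10 highest nuclear genes were Rn7sk at 5839 ± 2023, Gm42418 at 4805 ± 2006 and the pseudogenes Gm29216 at 6848 ± 879 and Gm28437 at 4506 ± 599. The values of both pseudogenes are uncertain, because unprocessed pseudogenes can share reads with the genes they copy.

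Genes of young neurons had the highest median of the cell type lists. All 16 genes of the young neuron list were detected, with a list median of 795 ± 103 TPM, and Tubb3 reached 2581 ± 213, the microtubule regulator Stmn1 1878 ± 400 and the growth cone gene Gap43 1332 ± 70.5. The 16 genes of mature neurons and synapses were detected too, at a lower median of 90.2 ± 4.32, with Map2 at 372 ± 0.891, the vesicle genes Vamp2 at 271 ± 27.1 and Syp at 247 ± 8.13, and the heavy neurofilament gene Nefh lowest at 6.01 ± 3.20. Cortical projection neuron genes had a median of 30.8 ± 4.88, led by Neurod6 at 175 ± 26.4 and Neurod2 at 61.3 ± 13.2. Genes of the GABA interneuron lineage had a median of 25.6 ± 5.73, led by the neuropeptide genes Sst at 358 ± 77.7 and Npy at 223 ± 68.0.

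Progenitor genes were present beside the neuronal ones. The radial glia list had a median of 31.4 ± 0.636, with Fabp7, a fatty acid binding protein of radial glia, at 1518 ± 120 and Vim at 377 ± 14.2. Intermediate progenitor genes were lower, at a median of 11.9 ± 0.424, with Gadd45g at 30.5 ± 4.06, Dll1 at 21.8 ± 0.318 and Neurog1 at 0.320 ± 0.0141. All 20 cell cycle genes were detected at a median of 15.01 ± 0.103, from Pcna at 113 ± 1.20 down to Cenpf at 3.42 ± 0.495.

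Glial genes ranged from abundant to hardly detected. The astrocyte list had a median of 30.9 ± 1.66, led by Apoe at 759 ± 98.5 and Aldoc at 137 ± 4.09, with S100b lowest at 6.05 ± 3.49. Genes of oligodendrocyte precursors had a median of 14.2 ± 2.60, led by Ptprz1 at 119 ± 1.59 and Olig1 at 100.8 ± 5.93. Of 11 genes of myelinating oligodendrocytes 6 were detected in both libraries, with a median of 1.89 ± 0.233. Mbp stood at 18.7 ± 4.62, while Opalin, the lowest, was at 0.01 in replicate 1 and 0 in replicate 2.

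Genes of vascular, immune and lining cells were also detected. Endothelial genes had a median of 13.9 ± 0.0177, with the tight junction gene Cldn5 at 105 ± 3.29 and the glucose transporter gene Slc2a1 at 67.5 ± 10.3. Pericyte and smooth muscle genes had a median of 5.79 ± 1.65, led by Rgs5 at 35.3 ± 0.955, and microglia and macrophage genes 6.08 ± 0.580, with C1qb at 24.3 ± 0.552. Ependyma and cilia genes had a median of 2.90 ± 0.0354, led by Foxj1 at 11.3 ± 2.23, and meninges and fibroblast genes 26.9 ± 5.57, led by Ptgds at 527 ± 133. The choroid plexus list had a median of 6.67 ± 4.11, and its leading gene, the thyroid hormone carrier Ttr, differed between the libraries at 427 and 1389 TPM.

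Genes of the telencephalon had the highest median of the regional lists, and most HOX genes were near 0. The telencephalon list had a median of 16.4 ± 1.88, led by Lhx2 at 88.2 ± 2.28. Diencephalon and hypothalamus genes had a median of 4.43 ± 1.03, led by Tcf7l2 at 89.8 ± 23.5 and the vasopressin gene Avp at 40.1 ± 11.7. Midbrain genes had a median of 2.85 ± 0.0707, led by Nr4a2 at 11.8 ± 1.49, and hindbrain and cerebellum genes 5.61 ± 0.389, led by Zic1 at 141 ± 30.2 and Zic2 at 21.6 ± 7.23. The spinal cord and motor neuron list had a median of 0.785 ± 0.544, with Isl1, also expressed in the forebrain, highest at 31.4 ± 9.72. None of the 15 HOX genes of groups 1 to 5, which are used from the hindbrain backwards, reached a TPM of 1 in both libraries. Hoxd3 was highest, at 0.05 in replicate 1 and 1.94 in replicate 2. The 12 HOX genes of groups 6 to 9 and the 12 of groups 10 to 13 had medians of 0.01 ± 0.0141 and 0, with Hoxd8 at 0.125 ± 0.0354 and Hoxd13 at 0.05 ± 0.0141.

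Receptor and guidance lists were broadly detected. Of 23 glutamate receptor genes 22 were detected, at a median of 20.3 ± 0.311, from Gria2 at 211 ± 10.3 to Grin3b at 0.340 ± 0.0283. Of 19 GABA and glycine receptor genes 17 were detected, at a median of 20.4 ± 1.63, led by Gabbr1 at 223 ± 9.02, with the cerebellar subunit gene Gabra6 at 0.0350 ± 0.0212. All 26 axon guidance genes were detected, at a median of 24.3 ± 2.52, led by Efnb3 at 166 ± 5.44 and Sema3f at 95.1 ± 14.5. The 22 neural RNA-binding and splicing regulators had a median of 66.7 ± 1.98, led by Rbfox2 at 202 ± 8.14 and Celf2 at 177 ± 20.1.

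Imprinted genes had a median of 58.4 ± 4.53, led by Nnat, Meg3 at 3218 ± 95.1 and Rian at 3170 ± 238. Neural long noncoding RNAs had a median of 197 ± 10.98, led by Meg3 and Rian too (2.77 RPKM as the list's median in the mm9 values), with Snhg11 at 676 ± 64.4 and Miat at 497 ± 86.1. Ribosomal protein genes had a median of 891 ± 1.48 (22.96 RPKM in the mm9 values) and mitochondrial-encoded genes 2655 ± 120 (0 RPKM). In the latter list mt-Atp8 stood at 56425 ± 5320 TPM, on 41914 and 77184 fragments and with deposited effective lengths of 13.3 and 14.2 nt, so this value rests on the length correction. Replication-dependent histone genes had a median of 4.12 ± 0.0636, led by Hist1h2bc at 51.7 ± 9.12. These are levels in RNA selected for poly-A tails and do not measure histone transcripts without such tails. Hypoxia and stress genes had a median of 34.8 ± 4.38, led by Ldha at 366 ± 12.98, and immediate early genes 5.08 ± 1.58, led by Jund at 92.5 ± 4.75.

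Y-linked genes were expressed in both libraries, whereas Xist, the noncoding RNA of the inactive X chromosome, was not above 0.0900 TPM in either. Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) stood at 65.2 ± 1.93, Kdm5d at 19.3 ± 0.438, Ddx3y at 14.5 ± 0.509 and Uty at 8.19 ± 0.636. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254) had 53 and 102 expected counts, and its overlapping antisense gene Tsix stood at 0.0550 ± 0.00707 TPM. The labels give both sexes for each sample.

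The age of the tissue was examined through 40 pairs of related genes entered as an earlier and a later member. NMDA receptor subunit gene Grin2b, the earlier form, stood at 21.7 ± 0.636 TPM against 1.03 ± 0.00707 for Grin2a. Glra2 stood at 42.5 ± 0.757 against 0.435 ± 0.0212 for Glra1, Dcx at 195 ± 8.26 against 22.4 ± 3.83 for Rbfox3, and Scn3a at 38.1 ± 0.728 against 14.5 ± 0.424 for Scn1a. Other pairs had the later member higher. The chloride exporter gene Slc12a5 stood at 99.1 ± 5.55 against 15.8 ± 0.707 for the importer gene Slc12a2, Dlg4 at 203 ± 21.7 against 41.7 ± 1.04 for Dlg3, and Map2 at 372 ± 0.891 against 149 ± 5.45 for Map1b. Adult globin genes far exceeded embryonic ones, with Hba-a1 at 442 ± 136 against 0.115 ± 0.0778 for Hba-x, though near-identical globin copies can share reads.

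By limma's intercept-only model with Benjamini-Hochberg adjustment, 28 of the 40 pairs were called with the first-entered member higher and 10 with it lower. Nes against Gfap (log2 ratio -0.12, adjusted p = 0.442) and Slc17a6 against Slc17a7 (log2 ratio -0.25, adjusted p = 0.107) were not called. In 5 pairs the entry put the later member first, an error found after the values were seen, and with these turned around the counts were 23 and 15. These 5 pairs had Ptbp2 at 118 ± 2.34 over Ptbp1 at 67.1 ± 4.20, Dnmt3a at 35.0 ± 0.742 over Dnmt3b at 2.52 ± 0.134, Actl6b at 251 ± 29.4 over Actl6a at 25.7 ± 0.467, Dpf1 at 103 ± 22.1 over Phf10 at 56.7 ± 0.0212, and Ss18l1 at 42.9 ± 4.50 over Ss18 at 28.6 ± 2.12. The p-values measure only the spread between these 2 libraries, and the fit gave every pair the same standard error of 0.15 although the pairs' own SDs ran from 0.01 to 0.70. Bcan over Ncan (log2 ratio of Ncan to Bcan -0.49) turned direction in the mm9 gene values, at 0.24. Over all 40 pairs the sign changed for 3 in the mm9 values and for 8 without length correction, among the latter this pair, Map1b/Map2, Vcan/Bcan, Pdgfra/Mbp and Igf2bp1/Igf2bp2. A sign change was counted whether or not the turned ratio was called. By limma, Nes/Gfap was called without length correction (log2 ratio 1.06, adjusted p = 0.00777), Dpf1/Phf10 was not (0.05, adjusted p = 0.808), and 5 pairs in place of 10 had the first-entered member lower.

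**Figure D1:**
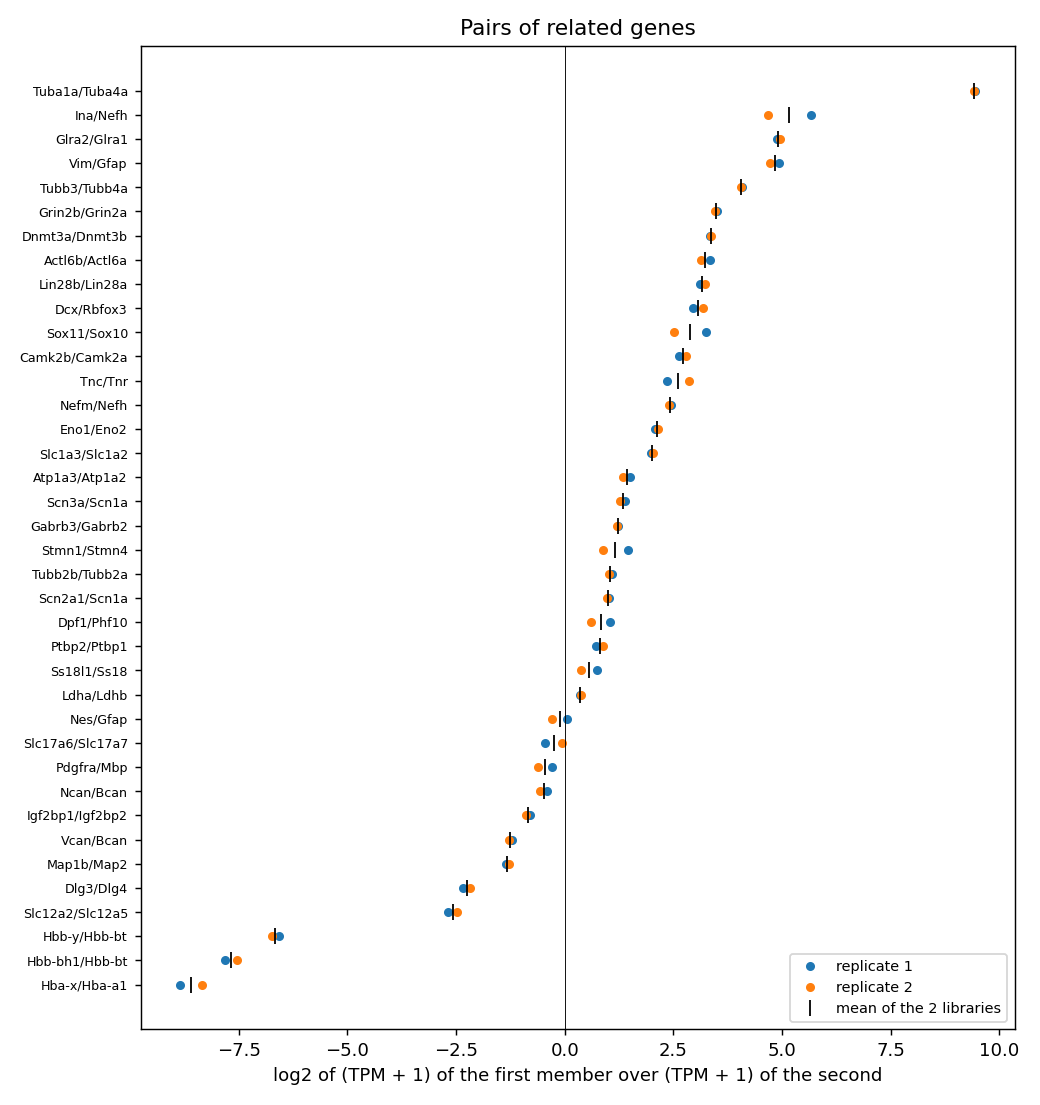
The 38 reported pairs of related genes, with the log2 ratio of the first to the second member (TPM + 1) on the horizontal axis; coloured points are the 2 libraries and the black tick their mean. Tuba1a over Tuba4a is highest at 9.43 and Hba-x over Hba-a1 lowest at -8.60; the pairs led by Ptbp2, Dnmt3a, Actl6b, Dpf1 and Ss18l1 show the later member first.

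The largest list ratios between the libraries were those of skeletal muscle, sensory ganglia, cartilage and bone, and choroid plexus. Skeletal muscle genes were higher in replicate 2, with a median ratio of 46.6-fold over 10 measured members, all of them higher. In the mm9 values, whose replicate numbers are not tied to these libraries, 6 measured members had a median of 5.83-fold, all in the same direction. This fold cannot be set beside 46.6-fold, because a pseudocount of 1 on the lower RPKM scale shrinks ratios. Members under a mean RPKM of 1 were left out there too. Acta1 stood at 10.2 TPM in replicate 1 and 167 in replicate 2, the fast light chain gene Mylpf at 1.40 and 166, and the creatine kinase gene Ckm at 0.230 and 94.4. Cartilage and bone genes (median 2.29-fold, 7 of 8 members higher) included the bone matrix gene Ibsp at 0.470 and 27.9. Sensory ganglion and neural crest genes (median 2.55-fold, 8 of 11 higher) included Prph at 5.56 and 42.5, but with 5 members measured in the mm9 values this list was not apart from random lists (median log2 ratio -0.11). The mm9 result covers only those 5 members, so it is not a check of the same set. Choroid plexus genes were 1.98-fold higher by the median, with all 7 measured members higher. Of the meninges and fibroblast genes, Col1a1 stood at 24.8 and 116, while the list's median ratio was 1.09-fold.

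Telencephalic lists, of which 2 hold genes of neurons, lay lower in replicate 2, by smaller amounts. The GABA interneuron lineage had a median log2 ratio of -0.43 (14 of 15 members lower), the telencephalon list -0.39 (11 of 12) and cortical projection neurons -0.29 (13 of 15). Bcl11b stood at 69.6 TPM in replicate 1 and 39.6 in replicate 2. The midbrain list lay lower too (-0.21, 7 of 10), the diencephalon and hypothalamus list (-0.07, 6 of 11) lay within the range of random lists, and the hindbrain and cerebellum list (0.15, with 6 of 10 higher) and the spinal cord list (0.48, with 5 of 7 higher) lay above it. In the spinal cord list Isl2 (6.79-fold), Prrxl1 (4.18-fold) and Tlx3 (3.28-fold) rose most. Chodl (1.39-fold) and Slc5a7 (1.24-fold) rose less, and Isl1 (0.77-fold) and Slc18a3 (0.75-fold) were lower. The median of this list alone therefore does not show more spinal cord tissue in replicate 2. With a trend on GC content and length removed, the midbrain list (-0.14) was no longer outside the range of random lists and the diencephalon and hypothalamus list (-0.17) was. Red blood cell genes had a median log2 ratio of -0.43, all 6 measured members being lower, and immediate early genes -0.28 (11 of 13 lower).

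Of 36 lists with at least 5 measured members, 25 had a median outside the central 95% of 10000 random lists matched on level, 14 above and 11 below, where chance alone would give 1.80. Many of these shifts were small. Astrocyte and cell cycle genes were 1.10-fold higher in replicate 2, oligodendrocyte precursor genes 1.09-fold, radial glia genes 1.05-fold and imprinted genes 1.03-fold, while the lists of mature neurons (median log2 ratio -0.11, 11 of 16 members lower), young neurons (-0.10, 11 of 16), axon guidance (-0.12, 19 of 26), neural RNA-binding and splicing regulators (-0.12, 15 of 22) and histones (-0.17, 4 of 7) lay lower. Several of these calls depended on the processing. With the trend on GC content and length removed, the medians of radial glia (log2 ratio 0.07 before and 0.02 after), axon guidance (-0.12 and -0.08) and mitochondrial-encoded genes (0.21 and -0.01) moved to within the random range, as the midbrain list did, and mature neurons stayed at about their value (-0.11 and -0.10) while the lower end of the random range went from -0.10 to -0.12. Microglia and macrophage genes (-0.13) and ribosomal protein genes (-0.17) were then below it, as was the diencephalon and hypothalamus list. In the mm9 values the lists of mature neurons, young neurons, cell cycle genes and RNA-binding and splicing regulators were not apart from random lists. Cell cycle genes (percentile 97.47, 13 measured members) and young neurons (percentile 3.045, 15 members) missed the limits narrowly there. List members that vary together can make such shifts more frequent than among random lists. With 1 library on each side the ratios have no replicate check and describe these libraries only.

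**Figure D2:**
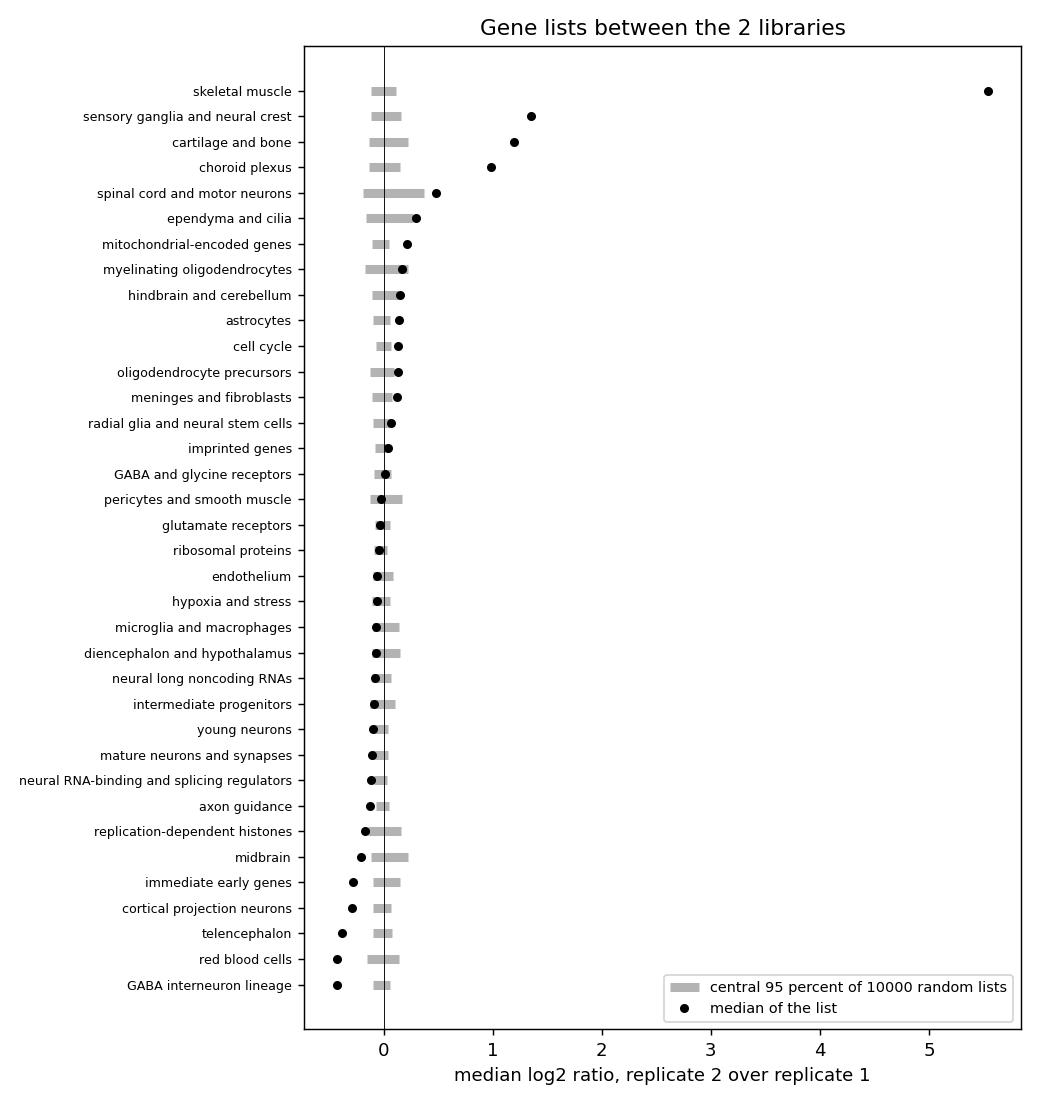
Median log2 ratio of each gene list, replicate 2 over replicate 1 (black points), with the central 95% of 10000 random lists of the same size and level (grey bars). Skeletal muscle stands at 5.54, and sensory ganglia, bone and choroid plexus follow between 0.98 and 1.35.

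Among single genes with a mean TPM of 5 or more, the 5 highest ratios in replicate 2 belonged to Ckm (log2 8.59), the pseudogene Gm10240 (0 and 333 expected counts), Actc1 (log2 7.07), Mylpf (log2 6.88) and Sln (log2 6.60), of which Ckm, Actc1, Mylpf and Sln are muscle genes. The 5 lowest were the keratin gene Krt6a (32.9 and 0.0300 TPM), the platelet chemokine gene Ppbp (184 and 0.380), the cornified envelope gene Cnfn (21.4 and 0.0300), Upk3bl (16.9 and 0.0600) and 2010109I03Rik (10.7 and 0.0900). Krt6a, Cnfn and Upk3bl had 5, 1 and 3 expected counts in replicate 2, so their ratios are imprecise.

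Levels across all genes were compared as well. Pearson's r of log2(TPM + 1) was 0.981 over 15627 genes, which are not independent replicates, and the biological coefficient of variation from edgeR was 19.1%. Its trend ran from 30.3% for the lowest of 4 groups of genes by level to 8.52% for the highest, and the median of the DESeq2 gene-wise estimates was 2.23%. A difference of at least 2-fold was seen for 445 of 15281 genes, 314 higher and 131 lower in replicate 2. Poisson sampling alone would give a mean of 23.95, a floor that holds no difference between samples and so does not say whether this count is large for separate samples. Such genes numbered 1471 at a mean TPM of 0.1 or more, 139 at 5 or more, and 294 as TPM ratios with a pseudocount of 1. Among multi-isoform genes at a gene TPM of 5 or more in both libraries, the most abundant isoform was the same for 7943 of 8359 (95.02%, exact 95% interval 94.5 to 95.5).

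**Figure D3:**
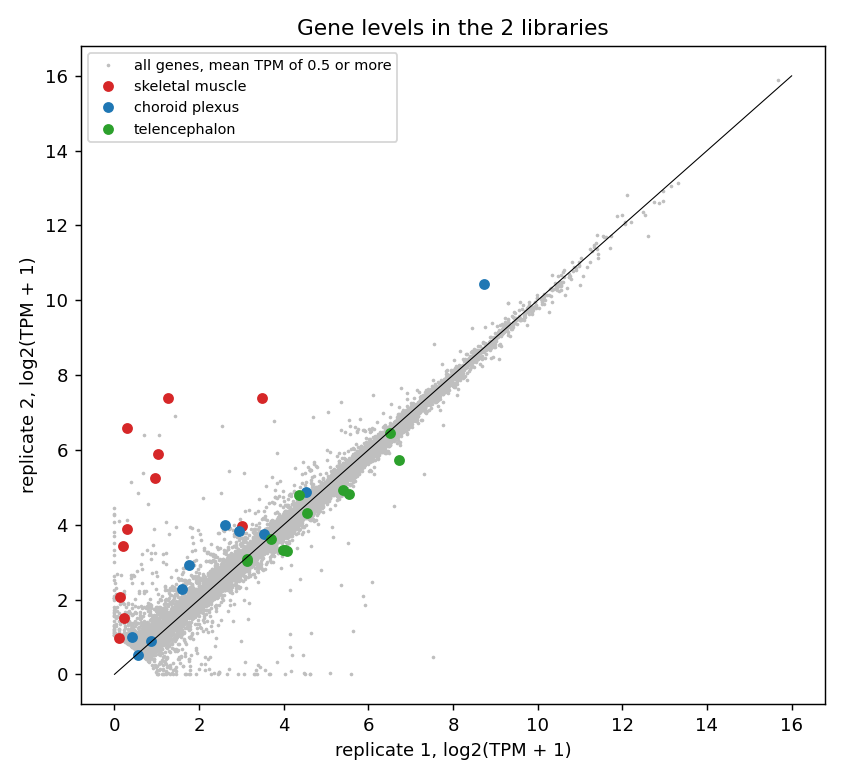
Gene levels as log2(TPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), for genes with a mean TPM of 0.5 or more (grey) and 3 of the lists (colours); the line marks equal levels. Skeletal muscle genes such as Ckm, at 0.230 and 94.4 TPM, lie far above the line.

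Alternative exons were read from junction counts on mm9, in 50 genes chosen for neural splicing. Several short exons were mostly included, such as the 18 nt exon of the kinase gene Src (chromosome 2, 157284579 to 157284596) at 77.0% (exact 95% interval 74.6 to 79.3), the 34 nt exon of Ptbp2 (chromosome 3, 119427530 to 119427563) at 93.5% (92.7 to 94.2) and the 54 nt exon of the clathrin light chain gene Clta (chromosome 4, 44043087 to 44043140) at 76.3% (75.5 to 77.0). Others were mostly skipped, such as the 168 nt exon of App (chromosome 16, 85043821 to 85043988) at 6.37% (5.91 to 6.84) and the 93 nt exon of Mapt (chromosome 11, 104179471 to 104179563) at 8.10% (7.48 to 8.74). The 110 nt exon of Dlg4, whose length is not divisible by 3, stood at 92.5% (91.7 to 93.3), and the 90 nt exons of Nrxn2 and Nrxn3 at 39.2% and 89.4%.

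In all, 113 exons in 45 of the 50 genes lay between 5% and 95%, and 95 of the 113 had a length divisible by 3. For the exon with the most junction reads in each of the 45 genes, the SD between replicates had a median of 1.48 percentage points and was highest for Mef2c at 18.2, on 42 junction reads. In 10 of these 45, among them Map2, Tpm1, Snap25 and Gria2, the inclusion junctions differed by more than 3-fold, so the percentage does not describe a simple cassette there. Without such cases 85 exons were left between 5% and 95%. This filter does not leave only simple cassettes, since the Gria3 exon it kept belongs to a mutually exclusive pair. The intervals cover counting error only.

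**Figure D4:**
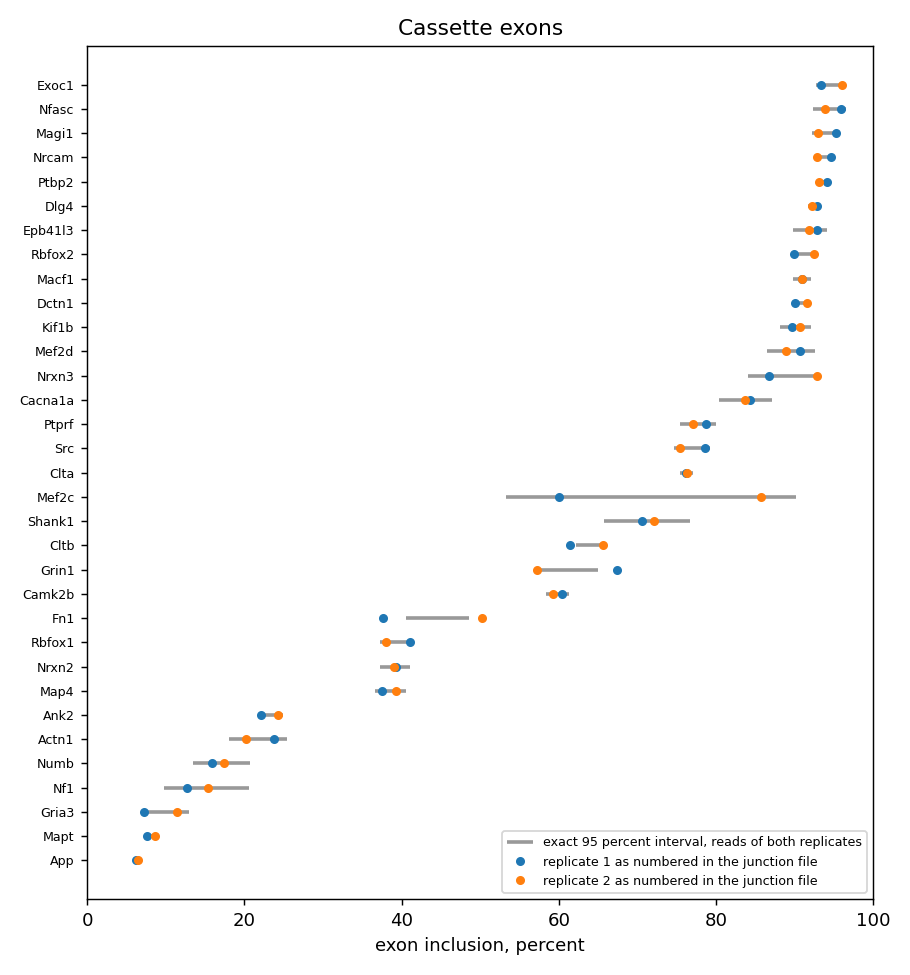
Inclusion in percent of the most covered alternative exon per gene, for 33 reported genes whose inclusion junctions lay within 3-fold of each other; points are the replicates as numbered in the junction file and bars the exact 95% interval of both together. App lies lowest at 6.37% and Mef2c has the widest interval.

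The mm9 gene values gave Pearson's r = 0.916 across 33068 genes against the mm10 FPKM values. The scales differed, with mm10 FPKM a median of 5.08 times the mm9 RPKM, so 9455 genes were at least 4-fold apart as deposited and 814 after scaling by that ratio. Mitochondrial genes such as mt-Co1 were listed at 0 in the mm9 table, and Gapdh stood at 1568 FPKM against 14.9 RPKM; both have near-identical copies elsewhere in the genome. These 2 genes were chosen after their values were seen. Outside the genes of the mm9 annotation, 152 de novo genes reached an RPKM of 1 in both replicates (3.47% of 4386), the highest at 242 ± 13.1 on chromosome 18 (mm9, 68851716 to 68851959). Of 159925 junctions with at least 10 reads in each replicate, 17792 (11.1%) were not annotated and 1776 lay outside every annotated gene, and 1999 of 38829 contigs did so too.

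Spike-in RNAs took 2.86% and 3.84% of the expected counts. Of 96 spike-ins 76 were above 0 in both libraries, with Pearson's r = 0.996 of their log2 TPM, and the median of their TPM ratios was 1.29, replicate 2 over replicate 1.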

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

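All tests in this part were chosen after the patterns were seen. Those of dilution, of the share of neurons, of the 3 telencephalic lists together and of embryos of a single sex were also written after their values were known, and the ranges from redrawing list members were added after the hindbrain and telencephalon values were seen, which without these ranges had argued against both explanations tested for them. The design holds 1 group, so beyond the tissue and the sex of the samples no biological explanation was tested.

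Reads of the phiX control genome, which no comparison uses, took 0.761% of all expected counts in replicate 1 and 0.178% in replicate 2, above the limit that a count of 0 allows.

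Skeletal muscle genes were far higher in replicate 2. A trend on GC content and gene length was argued against as the whole cause, since removing it left the median log2 ratio at 5.41 (5.54 before). The fitted trend was small over all genes, taking 2.29% of the variance of the log2 ratios and moving a gene by a median of 0.0488. A second list of 26 muscle genes, none of them in the fixed lists, had a median log2 ratio of 3.52 with all 19 measured members higher, among them Tnnc2 at 1.08 and 82.6 TPM, as muscle tissue in the sample of replicate 2 may give, and 9 of the 26 were at a TPM of 1 or more in replicate 1 too. Reads from libraries of other tissues cannot be told apart from it, because the liver list had a median log2 ratio of 0.27 and the heart list 1.51. The heart list shares Actc1 with embryonic skeletal muscle, while the cardiac gene Myh6 stood at 0.0600 and 0.0700 TPM.

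Xist stayed near 0 in libraries labelled as both sexes. Loss of Xist in a single quantification is argued against by the mm9 values, where Xist stood at 0.0256 ± 0.00495 RPKM against 1.06 for Uty, the lowest Y-linked gene. The highest Xist value of 0.0900 TPM, beside Y-linked genes of at least 7.74 TPM in each library, is what embryos of a single sex may give, as a hypothesis found in the same data. Loss of Xist during library preparation was not tested, a small share of female tissue is not excluded, and no other sample bears on the labels.

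The telencephalon, cortical projection neuron and GABA interneuron lists lay lower in replicate 2 (together 34 of 38 members lower, median log2 ratio -0.31), as did the midbrain list (-0.21), while the hindbrain and cerebellum list (0.15, 6 of 10 members higher) and the spinal cord list (0.48) lay higher and the diencephalon and hypothalamus list (-0.07) was not apart from random lists. In the spinal cord list Isl2, Prrxl1 and Tlx3 rose most, while Isl1 and Slc18a3 were lower. For the 3 telencephalic lists, dilution of neural RNA by other tissue was argued against as the whole cause, since it lowers neural genes alike, whereas the 12 neural lists without a region went both ways (young neurons -0.10 and RNA-binding genes -0.12 against astrocytes 0.14 and oligodendrocyte precursors 0.13, outside the random range with a GC and length trend removed too, unlike mature neurons -0.11, axon guidance -0.12 and radial glia 0.07) with a median of -0.03 over all members, and the 3 minus these gave -0.29 (95% range from redrawing members -0.43 to -0.14). A lower share of neurons could account for part of the fall, and whether it was the whole cause cannot be decided here. Young and mature neuron genes together fell less (median -0.10, 22 of 32 members lower), with a difference of -0.21 (-0.35 to -0.05). But these lists also hold genes higher in replicate 2, such as Nefh (2.21-fold), as the sensory ganglion list was (2.55-fold). Neurons from outside the telencephalon could thus offset a fall in these lists. For the 3 telencephalic lists, a trend on GC content and gene length was argued against as the whole cause too. Removing it moved other lists (mitochondrial-encoded genes from 0.21 to -0.01, ribosomal proteins from -0.04 to -0.17), ended 5 calls and brought 3 others. The removal left the median of the 3 at -0.30 (-0.49 to -0.21). All ranges from redrawing members treat them as independent and hold no spread between samples, so they may be too narrow where members vary together. The hindbrain and telencephalon medians differed by 0.54, and by 0.60 with that trend removed, but with ranges from -0.05 to 1.19 and from -0.03 to 1.20 their members are too few and too varied to decide, so for this difference dilution and the trend cannot be told apart from other causes, and a difference in the regions dissected was not tested.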

How the results depend on the processing

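Alternatives chosen after seeing the data are TPM rescaled over nuclear genes, the GC and length correction, leaving out lists of other tissue, the turned pairs, the scaled mm9 values and the balanced junctions. Counts of detected genes (10549 to 18635), of cassette exons (85 to 116) and of pairs with the first-entered member higher (23 to 30) stayed within 1.5 times of their main values. Replicate agreement moved to r = 0.961 with a pseudocount of 0.1, 0.994 with no filter, 0.972 at a TPM of 5 or more, 0.978 in the mm9 values and 0.983 as Spearman's rho. The coefficient of variation was 23.2% with no count filter and 2.23% as the median of the DESeq2 gene-wise estimates. The latter is a different statistic from the common dispersion of edgeR, so these values do not estimate the same quantity. How far this accounts for the gap was not tested. Genes differing 2-fold numbered 294 as TPM ratios with a pseudocount of 1, 1471 at a mean TPM of 0.1 and 139 at 5, and 422 without the lists of other tissue. Lists apart numbered 13 of 24 in the mm9 values, whose replicate numbers are not tied to these libraries, and 23 after the GC and length correction, and lists with a median of at least 1 numbered 21 in the mm9 values against 36, where the scale is lower, mitochondrial genes are listed at 0 and the medians of long noncoding RNAs (2.77 against 197) and ribosomal proteins (22.96 against 891) fell most among lists above 0, and the cause was not tested list by list. Pairs with the first member lower numbered 5 without length correction. There the sign changed for 8 of the 40 pairs, among them Nes/Gfap (1.06), Slc17a6/Slc17a7 (0.33), Map1b/Map2 (0.15), Vcan/Bcan (0.20), Ncan/Bcan (1.15), Pdgfra/Mbp (0.43) and Igf2bp1/Igf2bp2 (0.37), while Dpf1/Phf10 (0.05) lost its call, and in the mm9 values for 3 pairs, among them Ncan/Bcan (0.24) and Nes/Gfap (0.0442), where the cause was not tested. These sign changes were counted whether or not the turned ratio was called. The share of genes with the same main isoform was 93.9% at a gene TPM of 1 and 95.6% at 20. The correlation of the quantifications was 0.944 with a pseudocount of 0.1, 0.8003 for genes at 1 or more, 0.941 after scaling, and 0.913 to 0.916 with either library left out, and 814 genes were 4-fold apart after scaling, 160 higher in mm10 and 654 in mm9, against 9198 and 257 before. With minimums 5-fold higher, 45 de novo genes, 4423 unannotated junctions, 517 junctions outside genes and 440 contigs passed. For spike-ins with 10 or more counts r was 0.999. Leaving out a replicate was not run for replicate agreement, the coefficient of variation or ratios between libraries, which need both, and for pairs and list levels a single library differs from the mean of 2 by less than their SD by construction. With 2 libraries, no spread of any gene is known well.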

Other observations

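The lists and exons in this part were chosen after the data were seen. Mutually exclusive exons, which the cassette rule does not describe, were read from mm9 junctions in the same 50 genes. The pyruvate kinase gene Pkm used the left one of a pair of 167 nt exons (chromosome 9, 59522836 to 59523002) in 80.0% of reads (exact 95% interval 79.2 to 80.9) and the right one in 19.97%. Snap25 used the left 118 nt exon in 40.8% (39.1 to 42.5) and the right one in 59.2%. Its left exon stood at 44.9% and 38.3% in the 2 replicates of the junction file, so the interval, which covers counting error only, holds neither. The AMPA receptor genes Gria1 and Gria3 used the right one of their 115 nt exons in 80.6% (78.0 to 82.9) and 92.8% (90.2 to 94.7), so the cassette values of these exons do not describe simple skipping. Tpm1 used its left 76 nt exon in 92.1%, at 89.3% and 93.2% in the 2 replicates.

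Non-neural transcripts were present in replicate 1 as well. The epidermis list had a median log2 ratio of -0.56 (replicate 2 over replicate 1) with all 5 measured members lower in replicate 2, among them Krt14 at 20.98 and 0.420 TPM and Krt15 at 7.43 and 0.250. The second bone and mesenchyme list had a median log2 ratio of 1.15, with 16 of 17 measured members higher in replicate 2, and 13 of its 20 genes were at a TPM of 1 or more in replicate 1 too. Red blood cell genes included Hba-a2 at 1241 and 831 TPM, and retina and eye genes had a median of 0.448 ± 0.0247 with Cryaa at 1.48 and 0.150.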
